A study of Mus musculus with 8 samples.

How the data were processed

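RNA from hair follicle cells of mice of mixed strain was sequenced in 8 libraries, and the deposited tables of gene expression were used here. Per the labels' protocols, RNA was extracted with a Zymed kit and libraries were made at a core facility. Per the submitters' processing notes, TopHat and Cufflinks were used with the mouse build mm9; the versions of these tools are not given in the sources used here. The deposited values are FPKM (fragments scaled to transcript length and library size), with 1 column per library and no pooled columns, per the file headers. Whether the authors scaled libraries further is not given in the sources used here.

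The data came as 3 tables, each normalized separately. The table of hair follicle stem cells (HFSC) and that of transit-amplifying cells (TACs) from Shh-CreER mice each listed 22958 entries by RefSeq symbol. The table of TACs from hair bulbs of K15-CrePGR mice listed 45930 loci, of which 8904 carried no gene name and held between 78.4% and 79.0% of the summed FPKM of a library. Unnamed loci stayed out of the comparisons. Where a symbol appeared more than once, the entry with the highest mean was kept, and a locus that joins several genes stood in the gene lists for each of its symbols. All columns were matched to a sample by their names.

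Sequencing depth was not stated, and FPKM are not counts. Where few reads were counted, FPKM step by the worth of 1 read, so the most common ratio of values under 0.3 FPKM in both libraries gave their relative depth. The HFSC cKO library had 0.854 times the depth of its control, a ratio held by 324 of 2654 genes compared. The Shh-CreER libraries had a ratio of 1.003, held by 398 of 2459 genes. Relative to WT 52, the other K15-CrePGR libraries had 1.135 (WT 57, 194 of 3576 loci), 1.078 (KO 64, 146 of 2784) and 0.911 (KO 84, 134 of 2850) times its depth. From the same steps and the transcript lengths of GENCODE vM21, for transcripts over 1000 bp, depth came to about 55.6 M (Het) and 47.7 M (cKO) reads in HFSCs and 28.6 M reads in both Shh-CreER libraries. These depths are estimates, and no count model was fitted.

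In the K15-CrePGR TAC table, log2(FPKM + 1) of the 13565 named loci with a mean of at least 1 FPKM was tested with limma 3.58.1 (empirical Bayes with an intensity trend, two-sided) in R 4.3.3, comparing KO 64 and KO 84 with WT 52 and WT 57, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists of at least 3 kept members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists; an estimated correlation and fry were run beside it. The labels do not say that samples 52, 57, 64 and 84 are separate animals, so p-values measure only the spread between these samples. The HFSC and Shh-CreER tables hold 1 library per group, so no test was run on them. There, genes with a mean of at least 1 FPKM were counted when they differed at least 2-fold, and the median of each list was placed by its percentile among 10000 random lists of the same size matched on expression decile. Such percentiles describe these libraries only.

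The groups, the tests, the 36 gene lists, the rule for named genes and the alternatives of the processing were chosen before the data were examined, except where stated. The rule named Bmpr1a in every library, up to 4 members of each list with the largest difference among those with a mean of at least 5 FPKM (at least 1 where fewer than 2 reached 5), the 6 largest differences each way among genes with a mean of at least 5 FPKM and a symbol in the style of a protein-coding gene, and 12 genes for the comparison between tables. In the K15-CrePGR table too few genes passed the threshold, so the remainder were taken by rank of p and are given as not passing. Genes added after their values were seen are named as such, and some genes that the rule takes are not reported here.

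The K15-CrePGR procedure was tested on simulated data with 200 changed genes among the 13565. It called 0 of 67 genes changed 2-fold, 26 of 67 changed 4-fold and 40 of 66 changed 8-fold, with 4 unchanged genes called. Alternatives were another pseudocount (0.1 or 5), another filter, median scaling, quantile normalization, a fit without the trend, and each K15-CrePGR library left out in turn. Leaving out small RNA loci or loci at 0, and including unnamed loci, were added after the data were seen. An exact 0 in these tables can be a failed estimate, since genes that cells generally use were also at 0, so such genes are given as listed at 0. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.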

Results

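The series asked what the loss of Bmpr1a, a type I receptor for bone morphogenetic proteins (BMPs), does to the stem cells of the mouse hair follicle and to their rapidly dividing progeny, the transit-amplifying cells (TACs) of the hair bulb. Expression was measured by RNA sequencing in 8 libraries. Bulge stem cells (HFSCs) of K15-CrePGR mice were collected at postnatal day 68, with 1 control library (labelled Het) and 1 library of the deleted genotype (cKO). TACs of Shh-CreER mice were taken on day 68, again with 1 Het and 1 cKO library. TACs of K15-CrePGR hair bulbs were taken on day 80 from WT samples 52 and 57 and KO samples 64 and 84. Summed FPKM per library were 620905 and 649180 in HFSCs (Het, cKO), 511906 and 474109 in Shh-CreER TACs, and 4641743, 4584521, 3791914 and 4542419 in K15-CrePGR TACs (WT 52, WT 57, KO 64, KO 84), the last including unnamed loci. Values of the 3 tables were normalized separately, and genotypes were compared only within a table.

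Bmpr1a itself (mm9 chromosome 14, 35223828 to 35316539, the locus as listed in the K15-CrePGR table) was present in all 8 libraries. Its level was 31.8 FPKM in Het and 39.3 FPKM in cKO HFSCs, 46.0 and 40.4 FPKM in Shh-CreER TACs, and 39.7 ± 3.60 and 39.0 ± 1.36 FPKM (mean ± SD, n = 2 and 2) in K15-CrePGR TACs (log2 difference -0.02, limma adjusted p = 0.948, and 0.04 with quantile normalization). A value for the whole gene does not test the excision of a part of it, so these levels do not check the genotype labels. Transcripts of Id1, Id2, Id3 and Msx2, direct transcriptional targets of BMP signalling, were lower in each deleted library than in each control library of the same table. The sex-linked transcripts differed between libraries of a comparison: Xist, the X-inactivation RNA of female cells, was at 68.9 FPKM in Het and 3.98 FPKM in cKO HFSCs, and the Y-linked Ddx3y at 0.255 and 23.2 FPKM. In K15-CrePGR TACs, WT 52 had Xist at 3.26 and Ddx3y at 26.4 FPKM, while Xist lay between 175 and 226 FPKM in the other samples. Both Shh-CreER libraries expressed Xist and Ddx3y.

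**Figure D1:**
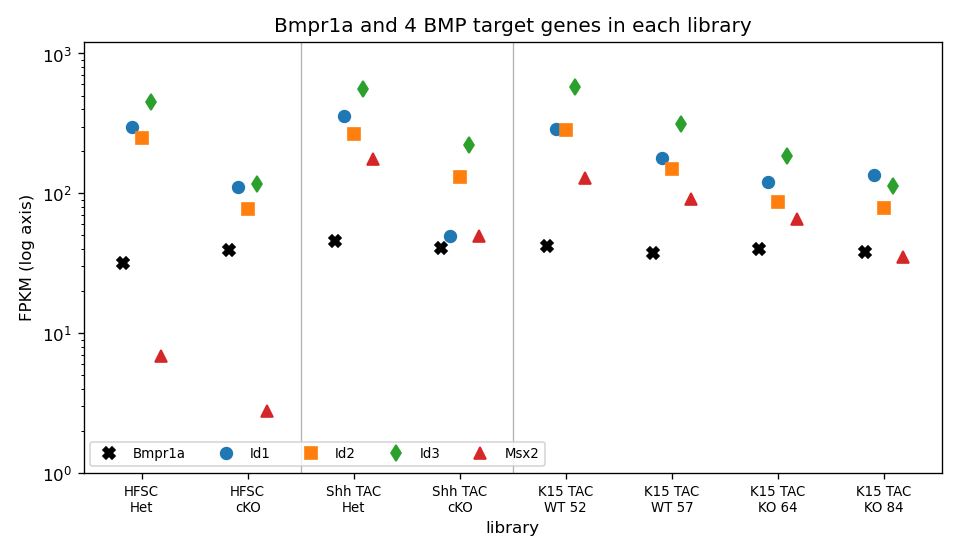
Each point is the FPKM (log axis) of Bmpr1a or of a BMP target gene in 1 of the 8 libraries, with vertical lines between the 3 separately normalized tables. Id3 lies at 447 FPKM in Het and 116 FPKM in cKO HFSCs, while Bmpr1a lies between 31.8 and 46.0 FPKM in all libraries.

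The first comparison asked how bulge stem cells differ without Bmpr1a. In the cKO library, transcripts of dividing cells were higher throughout: all 20 measured genes of G2 and M phase were at least 2-fold higher (median log2 difference 1.56), as were 17 of 20 genes of DNA replication (median 1.30). BMP target genes were lower, with 8 of 13 at least 2-fold lower and 1 higher (median log2 difference -1.08), and genes of cornified epidermis (10 of 13) and of sebaceous glands (7 of 11) were lower too. Hair shaft keratins, which bulge cells hardly express, were higher in the cKO library at low levels. There was 1 library per genotype, so none of these differences has a replicate check, and Xist and Ddx3y differed between the libraries as given above. Of 12205 genes, 722 were at least 2-fold higher and 562 at least 2-fold lower in cKO, 139 and 95 of them at least 4-fold.

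In what follows each pair of values gives the Het library first and the cKO library second. The antagonist gene Nog (38.2 and 2.32 FPKM) and the inhibitors of differentiation Id3 (447 and 116 FPKM) and Id2 (247 and 77.0 FPKM) were lower in cKO, and Id4 (41.9 and 118 FPKM) was higher; the list median lay at percentile 0. Among 14 components of the BMP pathway (median 0.27, mean -0.00), only the antagonist Grem1 (151 and 40.0 FPKM) differed 2-fold, while Bmp7 (24.6 and 46.5 FPKM), Smad1 (21.1 and 36.7 FPKM) and Acvr1 (10.7 and 16.8 FPKM) were higher by less. The mitotic genes Birc5 (5.44 and 28.1 FPKM), Cdk1 (3.91 and 18.0 FPKM), Ccna2 (5.42 and 23.5 FPKM) and Ccnb1 (5.51 and 23.5 FPKM) led the mitotic list. The replication genes Uhrf1 (5.76 and 27.2 FPKM), Mcm5 (7.65 and 28.3 FPKM), Rrm2 (11.2 and 37.4 FPKM) and Chaf1b (3.72 and 13.1 FPKM) led the replication list, and both list medians lay at percentile 100. Of 6 cyclin-dependent kinase inhibitors 1 was 2-fold lower, Cdkn1c (8.81 and 1.90 FPKM), with Cdkn1a (199 and 113 FPKM) lower by less and Cdkn2d (117 and 169.8 FPKM) and Cdkn2c (8.82 and 11.5 FPKM) higher (median -0.04).

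Markers of bulge stem cells split: 5 of 26 were at least 2-fold lower and 3 higher (median log2 difference -0.13, percentile 1.02). The growth factor Fgf18 (26.5 and 1.72 FPKM), the keratin Krt24 (365 and 46.1 FPKM), Angptl7 (321 and 57.3 FPKM) and the surface marker Cd34 (556 and 147 FPKM) were lower. Genes of the outer root sheath and companion layer were higher in 5 of 12 (median 0.69, percentile 100), led by the gap junction genes Gjb2 (4.46 and 132 FPKM) and Gjb6 (1.25 and 26.9 FPKM), Krt17 (1119 and 4127 FPKM) and Barx2 (92.7 and 230.2 FPKM). Of 6 hair shaft keratins 5 were higher (median 1.47), with Krt85 (0.0242 and 5.07 FPKM), Krt35 (0.141 and 5.18 FPKM), Krt33a (0.245 and 2.62 FPKM) and Krt83 (0.0984 and 1.91 FPKM). These 5 passed the filter only through the cKO library. Keratin-associated proteins were higher in 4 of 6 and lower in 1 (median 1.56), with Krtap17-1 (8.58 and 61.7 FPKM) higher and Krtap3-2 (22.1 and 1.46 FPKM) lower. The other higher ones (Krtap7-1, Krtap8-1 and Krtap11-1, named after their values were seen) passed the filter only through the cKO library. Genes of the preset inner root sheath list were higher in 4 of 9 (median 0.29), with Krt71 (1.48 and 10.9 FPKM) foremost. Its members Krt25 (6.18 and 7.79 FPKM), S100a3 (12.7 and 10.3 FPKM) and Gata3 (48.5 and 46.4 FPKM) were closer together. Markers of hair matrix TACs were higher in 3 and lower in 2 of 13 (median 0.41), with Ctsc (7.55 and 24.9 FPKM) and Hoxc13 (9.95 and 28.7 FPKM) higher, Dlx3 (10.2 and 3.77 FPKM) lower and Ptch1 (7.88 and 15.1 FPKM) higher by less than 2-fold. Hair lineage transcription factors were higher in 2 and lower in 3 of 14 (median -0.16), with Ovol1 (33.4 and 14.9 FPKM) lower.

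Among the epidermal differentiation genes, Lor (1119 and 42.0 FPKM), a main protein of the cornified envelope, Lce1b (99.5 and 6.88 FPKM), Lce1a1 (157 and 11.5 FPKM) and Spink5 (111 and 34.0 FPKM) were lower (median log2 difference -1.32). Sebaceous genes were lower (median log2 difference -1.37), including Scd3 (68.5 and 10.8 FPKM), Awat1 (16.1 and 3.65 FPKM), Cidea (33.4 and 8.44 FPKM) and Fa2h (64.3 and 18.0 FPKM). Immune genes were lower in 5 of 12 (median log2 difference -0.98), including H2-Ab1 (70.2 and 23.3 FPKM), Cd207 (19.2 and 7.08 FPKM), Cd74 (142 and 58.0 FPKM) and H2-Aa (68.7 and 31.9 FPKM). Smooth muscle genes were higher in 3 of 4 (median log2 difference 2.76), with Acta2 (0.691 and 23.2 FPKM), Tagln (1.72 and 23.2 FPKM) and Myl9 (8.49 and 48.1 FPKM). Melanocyte genes were higher in 4 of 5 (median 1.82), with Dct (2.59 and 21.2 FPKM) higher and Mitf (26.2 and 6.06 FPKM) lower. Fibroblast genes were higher in 3 of 6 and lower in 1 (median 0.95), with Sparc (215 and 433 FPKM) higher and Thy1 (11.6 and 9.33 FPKM) lower by less than 2-fold. Basal adhesion genes were higher in 4 of 18 and lower in 1 (median 0.36), with Tnc (8.23 and 86.3 FPKM), Col4a1 (13.2 and 53.1 FPKM), Col4a2 (16.5 and 37.7 FPKM) and Itgb6 (10.9 and 24.5 FPKM) higher. TGF-beta targets were lower in 3 of 10 and higher in 1 (median -0.45), with Ltbp2 (79.6 and 9.23 FPKM), Cyr61 (612 and 248 FPKM) and Smad7 (10.4 and 4.38 FPKM) lower.

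Of the remaining lists, wound and stress genes had 3 members at least 2-fold higher and 2 lower of 12, and hypoxia genes 3 and 1 of 15. Hedgehog genes had a median of 0.24, including Cdo (20.1 and 7.49 FPKM), Ptch1 (7.88 and 15.1 FPKM), Boc (63.5 and 36.1 FPKM) and Gli1 (13.3 and 23.1 FPKM). Wnt targets had a median of -0.17, including Axin2 (16.4 and 8.72 FPKM), Tcf7 (5.49 and 8.58 FPKM), Ccnd1 (23.3 and 32.6 FPKM) and Myc (97.9 and 76.2 FPKM). The Notch pathway had -0.16, including Hes1 (89.0 and 149 FPKM). Wound and stress keratinocyte genes (0.15) included Ereg (26.3 and 5.10 FPKM) and Hbegf (54.3 and 115 FPKM), and glycolysis and hypoxia genes (0.33) included Ndrg1 (115 and 45.7 FPKM), Eno1 (87.1 and 199 FPKM) and Pgk1 (206 and 457 FPKM). The isthmus and infundibulum list had a median of 0.53, with Lrig1 (49.8 and 124 FPKM), a marker of isthmus stem cells. Immediate early genes of tissue dissociation (-0.12, mean 0.00), interferon genes (0.07, mean -0.15), cholesterol synthesis (-0.28), ribosomal proteins (0.17), dermal papilla (-0.16) and Schwann cells (0.42) had the medians given, while endothelial, skeletal muscle, adipocyte and erythroid lists kept too few genes. Beside Gjb2 (given above) and Ube2h (given below), the largest single differences were higher Bgn (2.65 and 149 FPKM), the Y-linked Eif2s3y (0.551 and 51.7 FPKM), Nppc (5.85 and 148 FPKM) and Expi (0.136 and 22.6 FPKM). Among the lowest were Lce1m (430.4 and 23.5 FPKM), Lce1a2 (143 and 7.47 FPKM), Sncg (138 and 7.23 FPKM) and Cck (93.7 and 5.57 FPKM). Ube2h was listed at 0 in Het against 31.8 FPKM in cKO, and Ss18 at 58.8 FPKM against a listed 0.

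The comparison of TACs with Shh-CreER asked the same of the hair bulb. Transcripts of the hair shaft were much lower in the cKO library: 12 of 13 hair shaft keratins were at least 2-fold lower (median log2 difference -2.61), and their summed level was 5376 FPKM in Het and 508 FPKM in cKO. BMP targets were lower in 6 of 10 (median log2 difference -1.18) and hair lineage transcription factors in 9 of 15 (median log2 difference -1.17). Genes of the isthmus and of the sebaceous gland, regions above the bulb, were higher. With 1 library per genotype these differences have no replicate check. Of 12296 genes 328 were at least 2-fold higher and 340 lower, 44 and 82 of them at least 4-fold.

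The shaft keratins with the largest differences were Krt35 (3092 and 268 FPKM), Krt85 (1533 and 138 FPKM), Krt36 (95.5 and 8.65 FPKM) and Krt31 (213 and 25.9 FPKM) (Het then cKO). Keratin-associated proteins were lower in 6 of 13 (median -1.0), among them Krtap7-1 (880.3 and 86.1 FPKM), Krtap8-1 (1065 and 116 FPKM), Krtap11-1 (269 and 38.3 FPKM) and Krtap15 (77.8 and 12.3 FPKM). The transcription factors Hoxc13 (152 and 14.9 FPKM), a regulator of shaft keratin genes, Foxq1 (48.5 and 5.62 FPKM), Msx1 (59.5 and 8.05 FPKM) and Prdm1 (12.1 and 1.36 FPKM) were lower. The BMP target list also held Id1 (358 and 49.2 FPKM), Bambi (61.6 and 10.6 FPKM) and Msx2 (175 and 49.5 FPKM). Genes of the preset inner root sheath list were lower in 7 of 15 (median log2 difference -0.72, 95% binomial interval -2.18 to 0.52). Among these were S100a3 (822 and 109 FPKM), Dsg4 (41.2 and 5.67 FPKM), Tchhl1 (20.7 and 3.59 FPKM) and Tgm3 (34.3 and 6.80 FPKM). The list summed to 3042 and 2480 FPKM, a smaller fall than that of S100a3 alone. The inner root sheath keratins, singled out after their values were seen, differed less. Krt25 (546 and 589 FPKM), Krt71 (186 and 194 FPKM) and Krt73 (479.6 and 794 FPKM) were higher and Krt28 (421 and 254 FPKM), Krt27 (137 and 97.3 FPKM) and Krt26 (7.60 and 1.54 FPKM) lower. Matrix TAC markers were lower in 4 of 15 and higher in 2 (median -0.58), with Edar (14.1 and 52.5 FPKM) higher. Krt75 (111 and 12.9 FPKM) of the companion layer was lower while Barx2 (16.6 and 54.4 FPKM) was higher (outer root sheath list median 0.42, mean -0.02).

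Isthmus and infundibulum genes were higher in 3 of 6 (median log2 difference 1.42, summed 104 FPKM in Het and 737 FPKM in cKO), with the stem cell markers Lgr6 (3.92 and 46.6 FPKM) and Lrig1 (3.13 and 18.5 FPKM) and Krt79 (68.1 and 638 FPKM). Sebaceous genes were higher in 7 of 11 (median log2 difference 1.07), including Pparg (1.45 and 12.7 FPKM), a regulator of sebocyte and fat cell formation, Elovl3 (9.41 and 27.9 FPKM) and Fa2h (6.13 and 17.3 FPKM). Bulge stem cell markers were higher in 3 of 23 (median 0.31), Nfib (23.3 and 53.6 FPKM), Npnt (11.0 and 25.3 FPKM) and Sox9 (given below), while Nfix (27.9 and 54.4 FPKM) was higher and Lhx2 (13.9 and 6.75 FPKM) lower, both by less than 2-fold on FPKM + 1. Skeletal muscle genes, including Ckm (26.7 and 4.37 FPKM), Acta1 (36.1 and 6.26 FPKM), Tnnt3 (25.6 and 4.35 FPKM) and Tnnc2 (21.5 and 3.78 FPKM), were lower in all 8 members (median -2.27; summed 171 and 33.6 FPKM). The endothelial median was 0.53, smooth muscle -0.71, immune -0.43, melanocyte -0.23, with Dct (82.9 and 15.8 FPKM), Schwann 0.32, dermal papilla 0.23 and fibroblast 0.12, while adipocyte and erythroid lists kept 2 genes each.

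No gene of the DNA replication list (0.27) or of the mitotic list (0.14) differed 2-fold, with Gins2 (39.6 and 58.8 FPKM) and Cenpf (14.7 and 19.4 FPKM) the largest, and ribosomal proteins had a median of -0.31. Of the signalling lists, Fst (40.0 and 93.5 FPKM), an antagonist of activin and BMP, was higher in the BMP pathway list (median 0.12), and the hedgehog genes had a median of 0.10, with Gli1 (23.7 and 29.5 FPKM). Dkk4 (16.7 and 37.9 FPKM) was the foremost of the higher Wnt targets (0.20), Ctgf (6.58 and 35.3 FPKM) led the TGF-beta targets (0.10) and Heyl (12.8 and 2.65 FPKM), which was lower, the Notch pathway (-0.03). Basal adhesion genes had a median of 0.39. Epidermal differentiation had 0.10, with Calm4 (17.3 and 72.5 FPKM) higher and Ivl (30.9 and 9.56 FPKM) lower. Wound and stress genes had -0.41 (0.19 with a filter of 5 FPKM), with S100a8 (49.5 and 13.1 FPKM) and S100a9 (62.4 and 20.4 FPKM) lower. Hypoxia genes had 0.40, with Ndrg1 (27.0 and 89.8 FPKM) higher. Cyclin-dependent kinase inhibitors had 0.04, with Cdkn2a (2.36 and 9.66 FPKM) higher and Cdkn1a (167 and 65.1 FPKM) lower. Immediate early genes (0.08), interferon genes (0.07) and cholesterol synthesis (-0.08) differed little. The largest other differences were higher Lmo1 (8.43 and 113 FPKM), Slc16a1 (4.89 and 46.4 FPKM), Folr4 (1.44 and 17.1 FPKM) and Adh7 (4.41 and 38.0 FPKM). Lower were Gpnmb (322 and 27.8 FPKM) and Sct (46.2 and 3.25 FPKM); Srp54b stood at 34.6 FPKM in Het and was listed at 0 in cKO.

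In TACs from K15-CrePGR hair bulbs, taken with 2 samples per genotype, keratins of the hair shaft and genes of the inner root sheath were lower in the KO samples. Genes of the outer root sheath, of basal adhesion, of the isthmus and of bulge stem cells were higher. These calls rest on the preset correlation: for each of these 6 lists adjusted p = 0.559 with an estimated correlation. Values are means ± SD of WT and then KO samples (n = 2 and 2). Hair shaft keratins were below both WT samples in both KO samples for 10 of 12, with 8 lower when adjusted over the list alone (median log2 difference -1.69, adjusted p = 1.28e-05, and adjusted p = 0.559 with an estimated correlation). Among these were Krt31 (125 ± 17.8 and 17.9 ± 16.1 FPKM) and Krt36 (74.1 ± 14.1 and 11.5 ± 4.99 FPKM). Basal adhesion genes were above in 16 of 18, with 13 higher when adjusted over the list alone (median log2 difference 1.46, adjusted p = 2.05e-10, and adjusted p = 0.559 with an estimated correlation). Among these were the basement membrane genes Col4a1 (4.92 ± 0.546 and 46.7 ± 16.8 FPKM) and Lamb3 (1.39 ± 0.204 and 16.0 ± 3.64 FPKM). Chance puts both KO samples above both WT samples for 16.7% of genes, and below for as many; over all 13565 genes 26.8% (3642) were above and 27.5% (3737) below. By limma with Benjamini-Hochberg adjustment 9 of 13565 genes passed, 5 higher and 4 lower, 2358 had an unadjusted p under 0.05, and no member of any list passed over all genes.

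Of the 9 genes, Igfbp4 (17.8 ± 0.909 and 141 ± 16.7 FPKM), which binds insulin-like growth factors, rose and was above 0 in all libraries (log2 difference 2.91, SE 0.16, limma adjusted p = 0.0417). A further 7 were listed at 0 in both samples of 1 genotype: mt-Co1, AC132367.1 and Gm11084 in WT, and CT010479.2, Mir3100, Snord55 and Snord85 in KO. For mt-Co1, a mitochondrial gene, the KO samples had 5946 and 5271 FPKM (adjusted p = 0.000504). With WT 52 or with WT 57 left out 0 genes passed by limma (928 and 967 at an unadjusted p under 0.05), without KO 64 8 were higher and 7 lower, and without KO 84 18 and 5. Over the alternatives the adjusted p of Igfbp4 ranged from 0.0302 to 0.421. With 1 sample of a genotype, the lone sample is assumed to vary like the other group. Genes next by p did not pass. Bmp2 (2.91 ± 0.0958 and 25.8 ± 3.59 FPKM), a BMP ligand, Sdc3 (1.56 ± 0.214 and 16.0 ± 0.0588 FPKM), Mfap2 (1.82 ± 0.398 and 20.6 ± 1.95 FPKM) and Car2 (27.0 ± 1.30 and 2.55 ± 0.683 FPKM) had a limma adjusted p = 0.056. Dapl1 (1351 ± 16.1 and 284 ± 10.5 FPKM) and Fbp1 (56.2 ± 10.6 and 8.44 ± 1.35 FPKM) had 0.0734. At 0.0866 were Nkd2 (30.5 ± 0.612 and 10.2 ± 0.841 FPKM) and Acpl2 (15.9 ± 2.36 and 3.72 ± 0.496 FPKM).

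**Figure D2:**
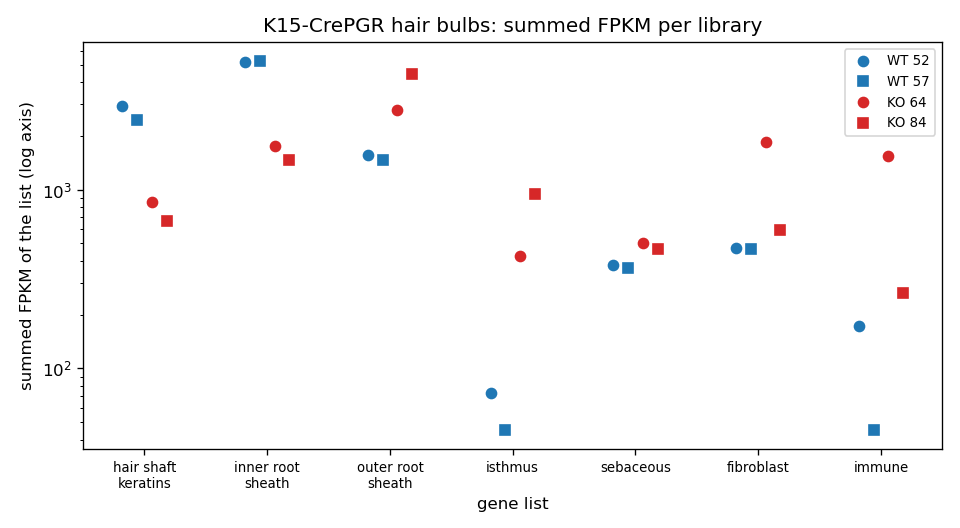
Each point is the summed FPKM (log axis) of a gene list in 1 K15-CrePGR library, with circles and squares for the samples of a genotype and blue for WT and red for KO. The immune list lies at 1552 FPKM in KO 64 and 265 FPKM in KO 84, against 172 and 45.0 FPKM in WT 52 and WT 57.

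By camera 17 of 35 lists were higher and 5 lower in KO at the preset correlation; with an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and 0 passed by fry. Inner root sheath genes were lower in both KO samples for 11 of 15, with 7 lower adjusted over the list alone (median log2 difference -1.37, adjusted p = 1.06e-05, and adjusted p = 0.559 with an estimated correlation). Among these were Krt25 (1278 ± 28.9 and 235 ± 94.4 FPKM) and Crym (50.1 ± 1.08 and 7.92 ± 7.37 FPKM). BMP targets were lower for 5 of 10, with none passing over the list alone (median log2 difference -0.83, adjusted p = 0.0268, and adjusted p = 0.625 with an estimated correlation). Among these were Id3 (444 ± 182 and 148 ± 50.9 FPKM), Id2 (215 ± 94.3 and 82.8 ± 5.56 FPKM) and Msx2 (109.9 ± 27.7 and 50.4 ± 21.4 FPKM). The BMP target list did not pass with no filter (adjusted p = 0.112), median scaling (0.0594) or quantile normalization (0.0842), without WT 52 (0.118) or without KO 84 (0.557). Mitotic genes were lower for 14 of 20, with none passing over the list alone (median log2 difference -0.31, adjusted p = 0.000806, and adjusted p = 0.617 with an estimated correlation). Among these were Ccnb2 (72.5 ± 9.11 and 51.4 ± 2.06 FPKM) and Cdk1 (219 ± 16.2 and 161 ± 1.58 FPKM), and without WT 57 the list did not pass (adjusted p = 0.0523). Ribosomal proteins were lower for 62 of 83 (median log2 difference -0.47, adjusted p = 3.41e-10, and adjusted p = 0.59 with an estimated correlation). Within that list Rpl23a (748 and 661 FPKM in WT, 122 and 2.50 FPKM in KO), Rpl7a (201 and 1097 FPKM in WT, 124 and 172 FPKM in KO), Rps3a (6.46 and 8.43 FPKM in WT, 4.03 and 128 FPKM in KO) and Rpl3 (44.0 and 2.27 FPKM in WT, 27.2 and 37.4 FPKM in KO) varied widely between samples of 1 genotype.

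Bulge stem cell markers were above both WT samples in both KO samples for 18 of 22, with 14 higher adjusted over the list alone (median log2 difference 1.28, adjusted p = 1.12e-08, and adjusted p = 0.559 with an estimated correlation). Among these were Postn (6.53 ± 1.59 and 59.6 ± 36.6 FPKM), Lgr5 (4.62 ± 1.32 and 26.1 ± 0.0555 FPKM) and Sox9 (2.62 ± 2.25 and 13.5 ± 1.46 FPKM). Outer root sheath and companion genes were higher for 9 of 11, with 8 adjusted over the list alone (median log2 difference 1.58, adjusted p = 3.56e-05, and adjusted p = 0.559 with an estimated correlation). Among these were Krt14 (112 ± 39.2 and 481 ± 107 FPKM) and Krt5 (476 ± 40.7 and 1513 ± 501 FPKM) of basal keratinocytes. All 6 isthmus and infundibulum genes were higher, and all 6 passed over the list alone (median log2 difference 2.45, adjusted p = 4.36e-06, and adjusted p = 0.559 with an estimated correlation). Among these were Krt79 (16.9 ± 3.12 and 479 ± 409.7 FPKM), Lgr6 (4.86 ± 1.38 and 31.7 ± 6.33 FPKM) and Lrig1 (5.16 ± 1.33 and 31.4 ± 0.385 FPKM). Sebaceous genes were higher for 7 of 9, 4 of them over the list alone (median log2 difference 1.70, adjusted p = 0.000354, and adjusted p = 0.559 with an estimated correlation). Among these were Acsbg1 (1.07 ± 0.304 and 14.2 ± 4.21 FPKM) and Plin2 (13.9 ± 0.327 and 48.7 ± 14.3 FPKM). Wound and stress keratinocyte genes were higher for 7 of 9, 6 of them over the list alone (median log2 difference 1.58, adjusted p = 0.00016, and adjusted p = 0.559 with an estimated correlation). Among these were Krt6a (12.1 ± 2.85 and 53.2 ± 20.6 FPKM) and Krt16 (2.97 ± 0.541 and 11.2 ± 4.25 FPKM). Hedgehog genes were higher for 7 of 10, 6 of them over the list alone (median log2 difference 0.94, adjusted p = 0.00227, and adjusted p = 0.559 with an estimated correlation). Among these were Gas1 (2.79 ± 1.64 and 10.3 ± 3.86 FPKM) and Gli1 (24.5 ± 7.69 and 53.4 ± 11.5 FPKM). Without KO 64 the list did not pass (adjusted p = 0.112).

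Markers of other cell types were higher as well, and immune and fibroblast sums were higher in KO 64 than in KO 84. Immune genes were higher for 12 of 12 (median log2 difference 2.63, adjusted p = 0.00016, and adjusted p = 0.617 with an estimated correlation). They summed to 172 and 45.0 FPKM in WT and 1552 and 265 FPKM in KO for WT 52, WT 57, KO 64 and KO 84. Fibroblast genes were higher for 12 of 13 (median log2 difference 1.98, adjusted p = 6.44e-05, and adjusted p = 0.617 with an estimated correlation). They summed to 472 and 465 FPKM in WT and 1859 and 593 FPKM in KO in the same order. The most abundant was Dcn (333 ± 69.2 and 421 ± 183 FPKM), followed by Col3a1 (24.0 ± 10.3 and 175 ± 167 FPKM) and Col1a1 (23.7 ± 18.6 and 170.0 ± 175 FPKM). Of the immune genes Cd74 (45.0 ± 41.9 and 338 ± 343 FPKM) was the most abundant. No immune or fibroblast gene passed over the list alone. Smooth muscle genes were higher for 5 of 6, 4 of them over the list alone (median log2 difference 1.56, adjusted p = 0.000528, and adjusted p = 0.559 with an estimated correlation). Among these were Acta2 (5.65 ± 1.24 and 37.1 ± 22.6 FPKM) and Myl9 (7.30 ± 2.07 and 33.2 ± 0.994 FPKM). Endothelial genes were higher for 5 of 8, 1 over the list alone (median log2 difference 1.23, adjusted p = 0.0143, and adjusted p = 0.617 with an estimated correlation). Melanocyte genes were higher (median log2 difference 1.12, adjusted p = 0.0149, and adjusted p = 0.625 with an estimated correlation). Schwann cell genes were too (median log2 difference 1.03, adjusted p = 0.0147, and adjusted p = 0.617 with an estimated correlation), as were dermal papilla genes (median log2 difference 0.88, adjusted p = 0.0143, and adjusted p = 0.625 with an estimated correlation). Erythroid genes were higher as well (median log2 difference 0.88, adjusted p = 0.00785, and adjusted p = 0.559 with an estimated correlation). None of the members of these lists passed over the list alone. TGF-beta targets were higher with 1 member higher and 1 lower over the list alone (median log2 difference 0.63, adjusted p = 0.0149, and adjusted p = 0.559 with an estimated correlation), the former Ctgf (4.01 ± 0.884 and 18.4 ± 2.86 FPKM). Interferon genes were higher with 2 over the list alone (median log2 difference 0.75, adjusted p = 0.0214, and adjusted p = 0.559 with an estimated correlation). Irf7 (4.03 ± 0.877 and 8.87 ± 0.956 FPKM) was among them. Without KO 64, the TGF-beta (adjusted p = 0.261), interferon (0.189), dermal papilla (0.727), melanocyte (0.231) and Schwann lists (0.13) no longer passed. Without WT 57 dermal papilla (0.0623) and Schwann lists (0.0648) did not pass. With quantile normalization interferon (0.0842) and Schwann lists (0.0629), and with a filter of 5 FPKM the dermal papilla list (0.145), did not pass. The endothelial list kept too few genes for a test without KO 64. With a filter of 5 FPKM the endothelial and Schwann lists kept too few as well.

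The other lists did not pass. Adjusted p was 0.186 for keratin-associated proteins (median -1.15), 0.075 for hair lineage transcription factors (median -0.56), 0.142 for BMP pathway components (median 0.15), 0.0555 for cholesterol synthesis (-0.24), 0.266 for immediate early genes (0.33), 0.46 for cyclin-dependent kinase inhibitors (0.18), 0.518 for DNA replication (-0.04), 0.518 for hypoxia genes (0.11), 0.518 for skeletal muscle (-0.05) and 0.882 for the Notch pathway (-0.04). For matrix TAC markers (adjusted p = 0.938) the median was -0.30 while the mean was 0.20 and camera pointed up. For Wnt targets (adjusted p = 0.905) the median was -0.07, the mean 0.07, with camera down and fry up. For epidermal differentiation (adjusted p = 0.635) the median was 1.12 and camera pointed up, while fry pointed down (adjusted p = 0.219). Some of these lists passed under an alternative. With a sample left out these were keratin-associated proteins (adjusted p = 0.000185 without KO 64, 0.0374 without WT 57), hair lineage factors (0.00352 without KO 64, 0.0287 without WT 57), DNA replication (0.00152 without WT 52), immediate early genes (5.73e-06 without WT 52) and cholesterol synthesis (0.00602 without KO 84). BMP pathway components passed with a filter of 5 FPKM (0.0311) or no filter (0.0489), cholesterol synthesis with median scaling (0.0453) or no filter (0.013), and immediate early genes with quantile normalization (0.0225). The adipocyte list kept 2 genes and was not tested.

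Across the 3 comparisons, list medians of BMP targets were below 0 in each, and those of shaft keratins in both TAC comparisons. In K15-CrePGR TACs these calls were lost, with adjusted p = 0.625 with an estimated correlation for BMP targets and adjusted p = 0.559 with an estimated correlation for shaft keratins, and the BMP target list also missed the threshold under the 5 alternatives given above. The genes named for this comparison were Id1, with log2 differences of -1.40 in HFSCs, -2.84 in Shh-CreER TACs and -0.83 in K15-CrePGR TACs, Id2 (-1.67, -1.02 and -1.29), Id3 (-1.94, -1.34 and -1.56) and Msx2 (-1.05, -1.80 and -1.15). Sox9, a factor of bulge and outer root sheath cells, was higher in all (1.00, 1.07 and 2.16), as was Shh (1.16, 0.84 and 1.58), near 0 FPKM in Het HFSCs. Lhx2, a bulge transcription factor, differed by -0.08, -0.94 and 1.96, Hoxc13 by 1.44, -3.27 and -0.78, and Foxn1 by -0.55, -0.86 and -0.45. Lef1 differed by 0.56, -0.74 and -0.62, Cd34 by -1.91, 0.08 and 1.94, and Gata3, joined with a neighbouring locus in the K15-CrePGR table, by -0.06, 0.64 and -0.01 (0.13 with quantile normalization). In the K15-CrePGR test none of these 12 genes passed, with limma adjusted p between 0.0917 (Lhx2) and 0.984 (Gata3).

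**Figure D3:**
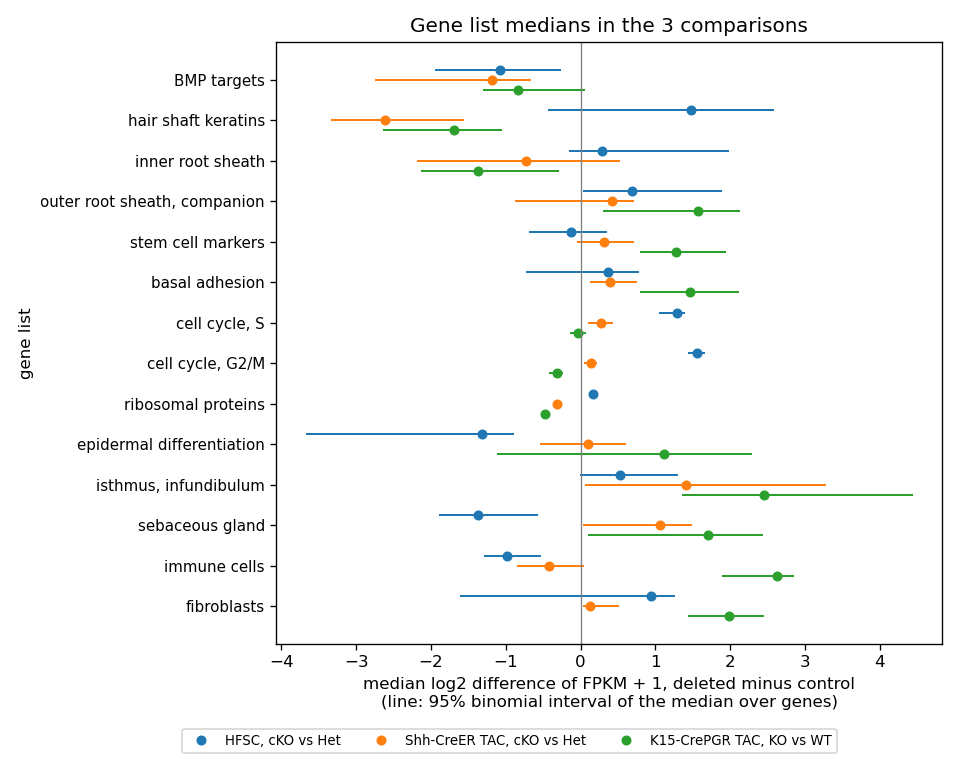
Each point is the median log2 difference of FPKM + 1, deleted minus control, of a gene list in 1 of the 3 comparisons, and its line is the 95% binomial interval of the median over genes. Hair shaft keratins lie at 1.47 in HFSCs, -2.61 in Shh-CreER TACs and -1.69 in K15-CrePGR TACs. The HFSC value rests on 6 keratins with summed levels of 8.24 FPKM in Het and 22.1 FPKM in cKO.

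Spearman's rho of the log2 differences across genes was 0.37 between the TAC comparisons (10680 genes; Pearson's r 0.32), -0.02 between HFSCs and Shh-CreER TACs (11261 genes; r 0.01) and -0.06 between HFSCs and K15-CrePGR TACs (10221 genes; r 0.04); genes are not independent replicates, so no p is given. Among genes differing at least 2-fold in both, the sign was shared by 86.6% of 238, 54.4% of 180 and 67.2% of 323 (47.2%, 51.0% and 60.7% with independent lists). In both TAC comparisons 131 genes were higher (24.0 with independent lists) and 75 lower (5.12 with independent lists). Between HFSCs and TACs, overlaps in opposite directions exceeded independent lists as well: 46 genes were higher in HFSCs and lower in Shh-CreER TACs (12.5 with independent lists) and 36 the other way (8.53), and for K15-CrePGR TACs these were 23 (8.88) and 83 (25.8), beside 62 (14.5) and 188 (48.8) higher and 36 (7.35) and 29 (4.70) lower in both. Of 10007 genes measured in all 3 comparisons 11 were at least 2-fold lower in each (0.082 with independent lists): Id2, Id3, Msx2, Ovol1, Alox12, Selenbp1, Gjb5, Hephl1, Ccdc64b, Dmpk and Gng13. A further 41 were higher in each (0.927 with independent lists), and Sox9, Lrig1, Barx2 and Wnt6 were among them. The names beyond the fixed genes were taken after the overlap was seen.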

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

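Among the tests below, those on sex and on depth in HFSCs were set down before their results were seen, and those on the hair bulb samples and on the shaft keratins were chosen or revised after the results had been seen. Differences between comparisons were not tested anywhere in this part.

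Gene lists and genes with opposite directions in different comparisons stood out. Hair shaft keratins had a median log2 difference of 1.47 in HFSCs against -2.61 in Shh-CreER and -1.69 in K15-CrePGR TACs. The HFSC median rested on 6 keratins at low levels, summing to 8.24 FPKM in Het and 22.1 FPKM in cKO. In Shh-CreER TACs the sums were 5376 and 508 FPKM. The 5 higher ones in HFSCs were at 0.314 FPKM or less in Het. They passed the filter only through the cKO library, so their rise was built in. Keratin-associated proteins had 1.56 in HFSCs (6 genes, summing to 33.6 FPKM in Het and 72.7 FPKM in cKO) against -1.0 and -1.15 in the TAC comparisons. Of the higher members in HFSCs, Krtap7-1 was listed at 0 in Het and at 2.29 FPKM in cKO. Krtap8-1 (0.0955 and 4.43 FPKM) and Krtap11-1 (0.124 and 1.97 FPKM) were close to 0 in Het too. These passed the filter only through the cKO library, so their rise was built in, and the median of 1.56 rests on them. Sebaceous genes had -1.37 in HFSCs against 1.07 in Shh-CreER and 1.70 in K15-CrePGR TACs. Epidermal differentiation genes had -1.32 in HFSCs against 1.12 in K15-CrePGR TACs, and immune genes -0.98 against 2.63. Smooth muscle genes had 2.76 in HFSCs, -0.71 in Shh-CreER TACs and 1.56 in K15-CrePGR TACs. Single genes did so too: Cd34 was at -1.91 in HFSCs and higher in both KO hair bulb samples, though mainly in KO 64. It was at 4.32 and 6.17 FPKM in WT, 50.9 FPKM in KO 64 and 9.77 FPKM in KO 84 (limma adjusted p = 0.31). Lef1 was at 0.56 in HFSCs, where its levels were low (0.813 FPKM in Het and 1.66 FPKM in cKO), and lower in both KO samples. Lhx2 hardly differed in HFSCs (-0.08), was at -0.94 in Shh-CreER TACs and was higher in both KO samples. Of these lists in K15-CrePGR TACs, keratin-associated proteins (adjusted p = 0.186) and epidermal differentiation (adjusted p = 0.635, with fry pointing down) did not pass. The others lost their calls, with adjusted p = 0.559 with an estimated correlation for shaft keratins, sebaceous and smooth muscle genes and adjusted p = 0.617 with an estimated correlation for immune genes. In the K15-CrePGR table, with unnamed loci included, 5 unnamed loci passed as lower and 1 as higher in KO.

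The first pattern was the 2-fold differences of HFSCs, where the libraries also differed in Xist and Ddx3y. A lower depth of the cKO library was argued against, since 46.3% (95% interval 43.6 to 49.0, n = 1283) of the genes had a mean of at least 10 FPKM, where sampling noise rarely reaches 2-fold. Of the 816 of these genes compared in both tables, Xist and Y-linked genes left out, 39.7% (36.4 to 43.1) moved the same way in WT 52 (Ddx3y high) against WT 57 (Xist high), under the bound of 60% set beforehand for counting sex out. That reading was withdrawn after the value was seen, because the bound rested on 1 sample per sex from another compartment, and sex effects may differ between bulge and bulb. Sex and genotype cannot be told apart with 1 library each, and an effect of genotype itself remains open and untested. Lists of other cells differed as well. All members of the epidermal differentiation (13 of 13), sebaceous (11 of 11) and immune lists (12 of 12) were lower in cKO. All members of the isthmus (7 of 7) and smooth muscle lists (4 of 4) were higher, while fibroblast, melanocyte, dermal papilla and Schwann lists split. Whether the cell makeup of the 2 libraries differed was not tested.

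The second pattern was the higher level of bulge, outer root sheath and other cell type genes in KO hair bulbs. More fibroblast, endothelial and immune cells as the whole source of its bulge, outer root sheath and isthmus genes were argued against. The summed rise over WT in KO 84 was 0.96, 2.30 and 2.43 times that in KO 64 for these lists. It was 0.69 or more with any gene left out and either WT sample as the base. For fibroblast, endothelial and immune genes it was 0.09, 0.19 and 0.11 (at most 0.27). The test replaced an undecided ratio of outer root sheath to immune sums. Smooth muscle genes were not part of it. They summed to 23.9 and 21.4 FPKM in WT and to 134 (KO 64) and 78.2 FPKM (KO 84). The sums do not speak for each bulge marker. Cd34 (50.9 and 9.77 FPKM) and Postn (85.5 and 33.8 FPKM) were higher in KO 64 than in KO 84, and Krt15 (246 and 341 FPKM) and Lhx2 (152 and 225 FPKM) lower. As the source of the fibroblast, endothelial and immune genes themselves dermal cells stayed open, since the smallest median of these lists, 1.23, which first counted in favour, only restates the pattern. Bulge cells at 1 share as the whole source of the bulge markers were first counted out, by a test on markers picked for being higher. The shares those markers need ran from 2.60% (Krt15) to 97.4% (Tcf7l1) with the Het HFSC profile (median 21.3%). With the cKO profile they ran from 4.76% (Postn) to 84.5% (Lhx2), with a median of 19.8%. A single share would make them alike, but how far gene levels differ between these tables for other reasons was not tested. The explanation was then left open. The median share used next still came from the markers picked for being higher. At that share, 10% (2.8 to 30.1) of 20 abundant bulge markers (Krt24 and Angptl7) lay over 10 times below the level that the Het HFSC profile would bring. With the cKO profile it was 9.1% of 22 (the same 2). Of all genes, 6.47% and 4.52% lay as far below the median ratio of these separately normalized tables. That ratio is another baseline than the median share, so these percentages are not like measures. More bulge or outer root sheath cells could also contribute, next to an untested change of cell identity with genotype. Of 361 genes at least 8-fold higher in Het HFSCs than in Het Shh-CreER TACs, 58.7% (53.6 to 63.7) were higher in both KO samples and 55 were lower in both. Among the 275 tested ones 58.5% were higher, against 26.8% of all tested genes. The first share lay between the bounds of 50% and 80%. An earlier count of 44.6%, which counted against such cells, had wrongly taken the 86 genes below the filter as not higher. The set also held genes of cornified epidermis and ribosomal proteins, such as Krt10 (4693 FPKM), Lor (1119 FPKM) and Rps4x (11652 FPKM) in Het HFSCs. Its share therefore cannot decide between bulge or outer root sheath cells and other sources. Without ribosomal genes it was 61.6% of 344.

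The third pattern was the lower level of hair shaft keratins in the Shh-CreER cKO library. A change of scale would move genes as a whole. The median was 0.01 over 12295 genes (joined loci left out) against -2.61 (-3.32 to -1.57) for the shaft keratins, so the FPKM held no such shift. FPKM are scaled to library size, which tends to hold that median near 0. The value could hardly have come out otherwise, and it is not counted as a test. It replaced a first test by median scaling (-2.63), which moved almost nothing. A smaller share of matrix cells of every lineage was first tested on the whole inner root sheath list, whose median of -0.72 (-2.18 to 0.52) did not settle it. The test was then narrowed, after that result, to 6 inner root sheath keratins, whose median of -0.22 (range -1.76 to 0.73) lay above that of the shaft keratins and argued against it as the whole cause. That exclusion rests on the narrower choice, and with 1 library per genotype an effect of genotype remains a hypothesis. Sums of other lists differed between the Het and cKO libraries too: isthmus (104 and 737 FPKM), sebaceous (215 and 407 FPKM) and skeletal muscle (171 and 33.6 FPKM). Whether the cell makeup of these libraries differed in other ways was not tested.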

How the results depend on the processing

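The alternatives named here were set before the data were examined, except those on loci at 0, small RNA and unnamed loci, which were added after. The cause was not tested where a result moved, except where fewer samples or genes entered. DESeq2 was not run because the values are FPKM, and no paired analysis was possible because the groups share no sample numbers. Depth limits low genes most, and it was only estimated.

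In K15-CrePGR TACs, 5 genes higher and 4 lower became 13 and 8 with a pseudocount of 0.1, and 3 higher with a pseudocount of 5 or without a trend, 2 higher with no filter, and 9 higher with a filter of 5 FPKM. Quantile normalization gave 4 higher and 5 lower. Leaving out 1 sample gave between 0 and 18 higher and between 0 and 7 lower: without WT 52 or WT 57 0 genes, without KO 64 8 and 7, and without KO 84 18 and 5. With only loci above 0 in all samples 0 and 0 passed by limma (2490 at an unadjusted p under 0.05), without small RNA loci 11 were higher, without both 8 were higher and 2 lower, and with unnamed loci 9 were lower. The 17 higher and 5 lower lists became 0 and 0 with an estimated correlation and 0 and 0 by fry, and the higher lists between 10 (without KO 64) and 18 when 1 sample was left out. Of the results of the 35 lists 464 kept direction and side, 61 lost and 12 gained the threshold, and 19 turned direction; of the named gene results 1474, 19, 16 and 11.

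Lists that turned had no call with all samples. Ranges with a sample left out cover every sample, including those whose removal did not turn the list. The lowest values of DNA replication (0.00152) and immediate early genes (5.73e-06) came without WT 52, where both kept direction and gained the threshold. The adjusted p of the lists that turned was as follows. Matrix markers: 0.8 with no filter, 0.492 to 0.915 with a sample left out. Keratin-associated proteins: 0.83 with no filter. DNA replication: 0.603 by quantile normalization, 0.00152 to 0.66 with a sample left out. Kinase inhibitors: 0.746 with a filter of 5. Wnt targets: 0.795 by quantile normalization, 0.979 by fry, 0.523 to 0.981 with a sample left out. Notch: 0.474 with a filter of 5, 0.786 by quantile normalization, 0.325 to 0.958 with a sample left out. Epidermal differentiation: 0.219 by fry, 0.274 to 0.915 with a sample left out. Immediate early genes: 5.73e-06 to 0.806, and skeletal muscle: 0.0523 to 0.945, with a sample left out. Genes that turned did not pass with all samples: log2 differences for the joined Gata3 locus were 0.13 by quantile normalization and between -0.32 and 0.30 with a sample left out, for Bmpr1a 0.04 and -0.11 and 0.07, for the joined Egfl7 locus 0.02 and -0.13 and 0.06, and with a sample left out for Bst2 -0.17 and 1.78, Rps3a -0.74 and 3.94 and Rpl3 -0.45 and 3.33.

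In HFSCs, 722 higher became 302 with a pseudocount of 5 and 436 with a filter of 5, and 562 lower became 278 with a pseudocount of 5. In Shh-CreER TACs, 328 higher became 527 (pseudocount 0.1), 119 (pseudocount 5) and 198 (filter of 5), and 340 lower became 173 (pseudocount 5), while the wound list turned to 0.19 with a filter of 5. Of the other list medians 175 stayed within their interval and 11 moved in HFSCs, and 193 and 7 in Shh-CreER TACs. The shared sign, 54.4% for HFSCs with Shh-CreER and 67.2% with K15-CrePGR TACs, lay above the 51.0% and 60.7% of independent lists where rho was below 0. With single samples rho lay between -0.07 and -0.01 for HFSCs with K15-CrePGR TACs and between 0.31 and 0.37 for the TAC comparisons, the latter being 0.41 with a filter of 5.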

Other observations

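Genes singled out here were chosen after their values were seen. In K15-CrePGR TACs Edar, a receptor of hair placode formation, was at 4.25 ± 2.40 FPKM in WT and 25.1 ± 9.43 FPKM in KO (limma adjusted p = 0.139, not passing), and Edar was also higher in the Shh-CreER cKO library (14.1 and 52.5 FPKM). Of the Notch ligands, Jag1 (133 ± 31.6 and 66.9 ± 17.4 FPKM) was lower and Jag2 (20.2 ± 6.83 and 47.6 ± 20.6 FPKM) higher in KO, and neither passed the test (adjusted p = 0.224 and 0.266). Of the epidermal genes Krt2 (9.25 ± 0.0598 and 0.273 ± 0.0434 FPKM) was lower while Krt10 (15.8 ± 7.74 and 91.0 ± 71.0 FPKM) was higher (adjusted p = 0.0597 and 0.24), neither passing.

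Selenbp1 and Alox12 were among the genes at least 2-fold lower in all 3 comparisons. Selenbp1, a selenium-binding protein, was at 28.3 and 7.29 FPKM in HFSCs, 32.5 and 3.38 FPKM in Shh-CreER TACs, and 404 and 263 FPKM in WT against 77.7 and 60.8 FPKM in KO hair bulbs. Alox12, a lipoxygenase, was at 7.69 and 3.04 FPKM in HFSCs, 34.4 and 4.52 FPKM in Shh-CreER TACs, and 14.1 and 14.1 FPKM in WT against 4.55 and 3.72 FPKM in KO hair bulbs. Levels of the 3 tables were normalized separately.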
